A study of Homo sapiens with 12 samples.

How the data were processed

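Messenger RNA of HCT116 cells was sequenced in 12 libraries: control (GFP), NSE4A-flag (NSE4) and SMC5-flag (SMC5) transfected cells, each given PBS or doxorubicin, with 2 libraries per group. The submitters' processing notes name TopHat and Cufflinks, with no versions and no genome build, as the tools behind the deposited FPKM values. The deposited table holds 57908 loci by 12 columns of FPKM, and all 12 columns were used. Of these loci 52952 are named by 1 gene, 3405 by several and 1551 by none. Of the 49368 distinct single names 46400 are in GENCODE 29. That annotation and a RefSeq one served only for gene names, gene types, lengths and GC content. Because the build is not given in the sources used here, no coordinates are printed. A spreadsheet had turned 12 gene names into dates, and these loci were not named. None of the values of 7 housekeeping loci was 0, and 52 of the 7439 loci with a mean FPKM over 10 had a 0 in some library.

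Depth was estimated from the FPKM steps of single fragments in transcripts of at least 1500 bases, at 13.81 M (1e6 fragments) for GFP replicate 2 up to 19.07 M for NSE4 replicate 2. The 2 columns of doxorubicin-treated SMC5 cells had a Pearson r of 0.99943 on the log2(FPKM + 1) scale, against 0.98682 to 0.98805 in the other 5 pairs. They held 1091 identical values above 0, against 0 in the other pairs, and the SD of their log2 ratio at 0.1 to 0.3 FPKM was 0.153 against 1.256 to 1.304. Their ratio followed GC content (Spearman rho −0.859 over 10 FPKM), as did that of the other 5 pairs, less closely (−0.307 to −0.592). Separate libraries at this depth would differ more by sampling alone, so their mean was used as 1 sample. This departs from the 12 samples of the design and leaves 11 samples.

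Values were tested with limma 3.58.1 in R 4.3.3 as log2(FPKM + 1), with all 6 groups in 1 fit, an intensity trend in the prior variance and 5 residual degrees of freedom. Loci with an FPKM of at least 1 in at least 2 samples were kept, which left 15833, of which 12307 have a symbol used once among them. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05, and "rose", "fell" and "called" refer to it. Fold changes on this scale understate changes of genes with low FPKM. Nothing in the sources says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

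The 11 comparisons were doxorubicin in each of the 3 backgrounds, each plasmid against GFP cells without and with doxorubicin, the 2 interactions, and NSE4 against SMC5 cells without and with doxorubicin. The median SE of a log2 fold change was 0.166, 0.204 where the lone SMC5 sample enters, and 0.235 and 0.263 for the interactions. In data simulated with the same spread, with 100 loci changed by each size, 77% of 2-fold and 99% of 4-fold changes were recovered for doxorubicin in GFP cells, 42% and 90% in SMC5 cells, and 80% and 95% for NSE4 without doxorubicin. Between 5 and 8 unchanged loci were called, and 0 changed loci were called in the wrong direction.

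Gene lists, written before the data were examined, were tested with camera at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Of 475 members in 25 lists 474 have a locus and 358 were tested. A list was tested if at least 3 of its loci were. Members whose locus also names another coding gene were left out (47), a choice made after the table was seen. Counts "adjusted over the list alone" adjust p-values within the list.

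The comparisons, the test, the filter, the lists and the rule for naming genes were set before the data were examined. The rule names SMC5, NSMCE4A and other SMC5/6 members, the 10 largest rises and falls with no overlap between samples and a mean of at least 1 FPKM in a compared group, up to 4 members of smallest p per list, CDKN1A and MDM2 after doxorubicin, and every called locus where fewer than 10 were called. For interactions the overlap criterion was not used. Some genes that the rule names are not reported here. Taking only loci with a single symbol used once for the 10 largest was decided after the table was seen.

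Alternatives tried were 2 scalings, 2 filters, another pseudocount, a replicate block, a fit on the compared groups alone, a fold threshold, leaving out each library in turn, the 12 columns as separate samples, protein-coding loci alone, values adjusted for GC content, and loci above 0 in every sample. Shared calls of the 2 plasmids were compared with 100 simulations of groups that share the GFP libraries.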

Results

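Messenger RNA of HCT116 cells, an established human colorectal carcinoma line, was sequenced after transfection with 1 of 3 plasmids and treatment with doxorubicin or vehicle. The SMC5/6 complex is a ring-shaped ATPase of the cohesin and condensin family that acts in DNA repair and chromosome segregation. SMC5 is 1 of its long coiled-coil arms, and NSE4A, the product of NSMCE4A, is the kleisin subunit that closes the ring. Doxorubicin is an anthracycline that intercalates into DNA and traps topoisomerase II on it. Cells received a control plasmid (GFP cells: the sample titles say GFP, the design text an empty vector), an NSE4A-flag plasmid (NSE4 cells) or an SMC5-flag plasmid (SMC5 cells). After 24 h each transfected culture was divided and given PBS or 1000 nM doxorubicin for 24 h, which made 6 groups of 2 libraries. The stated purpose was to learn how the SMC5/6 complex restrains growth and favours cell death after doxorubicin.

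The deposited table gave FPKM values for 57908 loci in 12 libraries. Between 23635 and 26185 loci were above 0 in a library, and the spacing of low values put the depth at 13.8 to 19.1 M (1e6) fragments. The locus that holds MT-ATP6, MT-ATP8 and MT-CO3, mitochondrially encoded respiratory chain genes, took 16.6 to 33.0% of the summed FPKM of a library. The 2 libraries of doxorubicin-treated SMC5 cells differed by less than the sampling noise and were counted as 1 sample: 7 loci were above 0 in only 1 of them, against 4216 to 5291 loci in the other 5 pairs. Values below are mean ± SD with n = 2 in each group, except in doxorubicin-treated SMC5 cells, where n = 1 and no SD can be given.

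**Figure D1:**
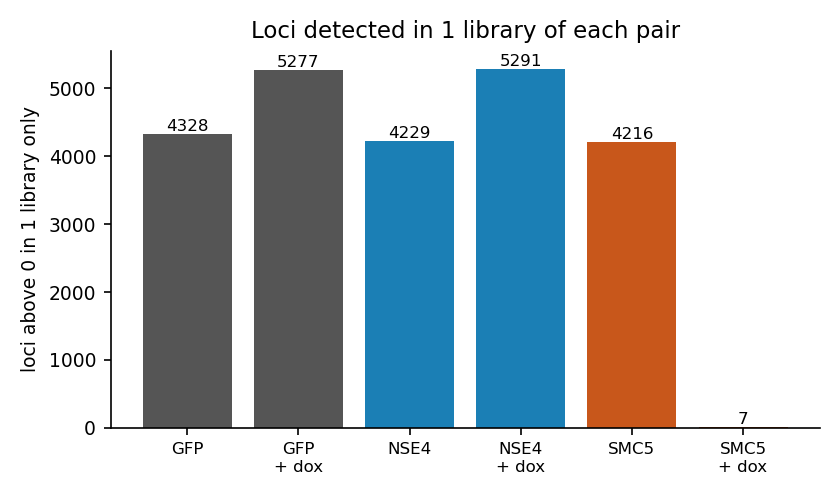
Number of loci above 0 FPKM in only 1 of the 2 libraries of each group (bars, 1 per group; dox, doxorubicin). The count was 7 in doxorubicin-treated SMC5 cells and 4216 to 5291 in the other 5 groups.

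The plasmid-encoded genes were examined first in every group. NSMCE4A stood at 71.8 ± 4.31 FPKM in GFP cells and 4128 ± 82.1 FPKM in NSE4 cells (SD, n = 2), and at 87.5 ± 2.60 and 5785 ± 710 FPKM after doxorubicin. It rose by 5.83 on the log2 scale without doxorubicin (SE 0.14, limma adjusted p = 9.03e-07) and by 6.02 with it (adjusted p = 4.46e-07). SMC5 stood at 21.1 ± 17.5 FPKM in GFP cells and 927 ± 73.7 FPKM in SMC5 cells, and at 12.8 ± 8.19 and 811 FPKM after doxorubicin. Its log2 differences of 5.66 (SE 0.75, adjusted p = 0.27) and 6.02 (SE 0.92, adjusted p = 0.272) did not pass the test over all loci, although every SMC5 library lay far above every other library. SMC5 was uneven in the cells without its plasmid, at 33.5 and 8.76 FPKM in the GFP libraries and 8.63 and 34.4 FPKM in the doxorubicin-treated NSE4 libraries. Adjusted over the list alone, the 9 SMC5/6 complex and loader genes, SMC5 passed in SMC5 cells with and without doxorubicin. With the 12 columns entered separately, SMC5 passed over all loci in doxorubicin-treated cells (adjusted p = 0.004). That fit counts 1 sample as 2, so its p-value is too small and adds no support.

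**Figure D2:**
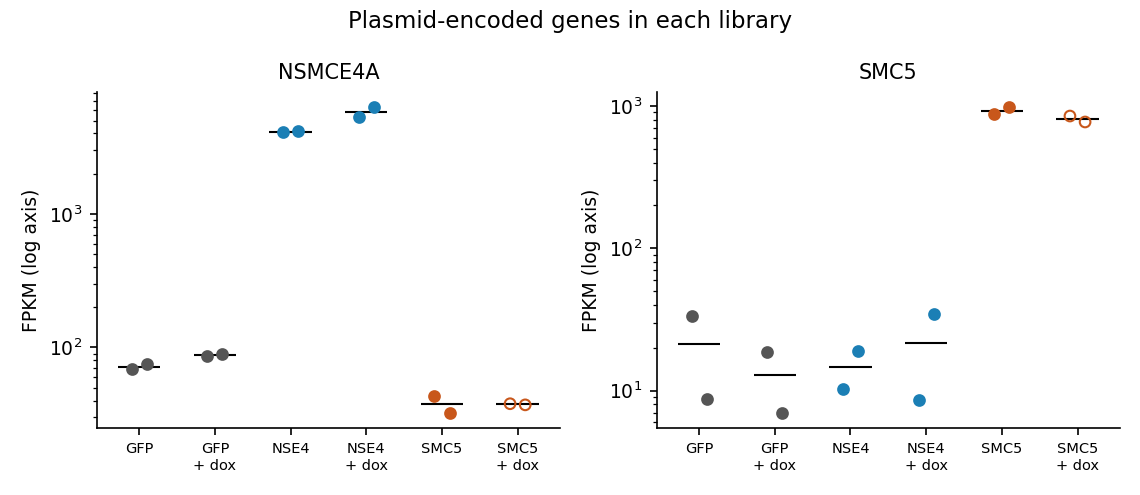
FPKM (log axis) of NSMCE4A and SMC5 in each library (points) by group; the horizontal line is the mean of the 2 columns of a group, and open points are the 2 columns counted as 1 sample. NSMCE4A was near 4128 and 5785 FPKM in NSE4 cells without and with doxorubicin, and SMC5 near 927 and 811 FPKM in SMC5 cells.

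Doxorubicin raised p53 target genes and lowered genes of cholesterol synthesis in GFP cells. Of 29 p53 target loci 27 rose, and of 16 cholesterol synthesis loci 15 fell. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 324 ± 46.4 to 994 ± 126 FPKM (SD, n = 2 in each group; log2 change 1.61, SE 0.13, adjusted p = 1.06e-04). Among single genes H19, an imprinted long noncoding RNA, rose from 5.07 ± 0.883 to 124 ± 7.72 FPKM, and MALL, a membrane raft protein of the MAL family, fell from 76.9 ± 7.19 to 6.04 ± 0.466 FPKM. In limma's test 2691 loci rose and 2228 fell of 15833 tested (6708 at an unadjusted p under 0.05). A change of at least 2-fold on the log2(FPKM + 1) scale was seen in 791 of the risen and 468 of the fallen loci. This comparison asks what doxorubicin alone does to the transcriptome of these cells. Fitted on the 4 libraries compared alone, the count was 3168, and it was 3000 without GFP replicate 1, 2936 without GFP replicate 2 and 2964 without GFP replicate 2 with doxorubicin. Rises outnumbered falls here, but falls outnumbered rises under quantile normalization (2693 rose, 2822 fell) and without GFP replicate 2 with doxorubicin (1463 and 1501).

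The log2 rise of H19 was 4.37 (SE 0.17, adjusted p = 1.14e-05). PGF, a placental growth factor of the VEGF family, rose from 5.50 ± 0.410 to 72.1 ± 15.9 FPKM (log2 change 3.48, adjusted p = 2.68e-05). AKR1B10, an aldo-keto reductase, rose from 0.263 ± 0.117 to 12.2 ± 2.22 FPKM (3.38). CDIP1, a p53-responsive cell death gene, rose from 3.96 ± 0.0816 to 44.2 ± 10.3 FPKM (3.17). RN7SK, the RNA of the 7SK particle that holds the elongation factor P-TEFb, went from 45.1 ± 2.10 to 579 ± 352 FPKM (adjusted p = 0.0261), but did not pass when any 1 of the 4 libraries was left out (adjusted p = 0.0586 to 0.142). AC032044.2 was listed at 0 in the PBS libraries and at 89.1 and 70.6 FPKM after doxorubicin, and SNORD91A, a small nucleolar RNA, at 0 and then at 69.2 and 53.3 FPKM. AC073107.2 was likewise listed at 0 and then at 9.64 and 7.75 FPKM. Here and below, whether a listed 0 means an absent transcript was not tested. AL138831.1 (20.7 and 35.3 FPKM after doxorubicin, listed at 0 before) passed at 0.0129, but not without GFP replicate 1 (0.0626), GFP replicate 2 (0.0631) or GFP replicate 2 with doxorubicin (0.0806). AC233728.1 (18.7 and 14.7 FPKM after doxorubicin, listed at 0 before) passed at 0.0498 and with none of the 4 libraries left out (0.147 to 0.165).

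The log2 fall of MALL was −3.47 (SE 0.12, adjusted p = 6.81e-06). FGFBP1, a secreted carrier of fibroblast growth factors, fell from 14.99 ± 2.82 to 1.41 ± 0.0517 FPKM (log2 change −2.72). RPL22L1, a paralogue of the ribosomal protein gene RPL22, fell from 441 ± 21.5 to 73.6 ± 6.42 FPKM (−2.57), and WNT16, a secreted Wnt ligand, from 103 ± 3.87 to 17.1 ± 0.351 FPKM (−2.51). FOS, a subunit of the AP-1 transcription factor, fell from 203 ± 88.9 to 35.1 ± 6.96 FPKM (−2.44, adjusted p = 0.00222). PDSS2, an enzyme of coenzyme Q synthesis, was at 47.5 and 7.99 FPKM before and 3.15 and 3.05 FPKM after doxorubicin (adjusted p = 0.0377). Its call was lost without GFP replicate 1 (0.17) and without either doxorubicin-treated GFP library (0.124 and 0.137). RPL37AP8, a ribosomal protein pseudogene, was listed at 0 after doxorubicin and at 5.52 and 3.18 FPKM before (adjusted p = 3.65e-04). AC016292.2 (22.0 and 28.5 FPKM before) and AC005899.3 (4.82 and 4.89 FPKM before) were also listed at 0 after doxorubicin, but did not pass with any 1 of the 4 libraries left out (adjusted p = 0.135 to 0.163 and 0.0863 to 0.0928). RN7SKP242 (10.4 and 3.20 FPKM before, listed at 0 after) did not pass without GFP replicate 1 (0.165) or either doxorubicin-treated GFP library (0.105 and 0.113).

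**Figure D3:**
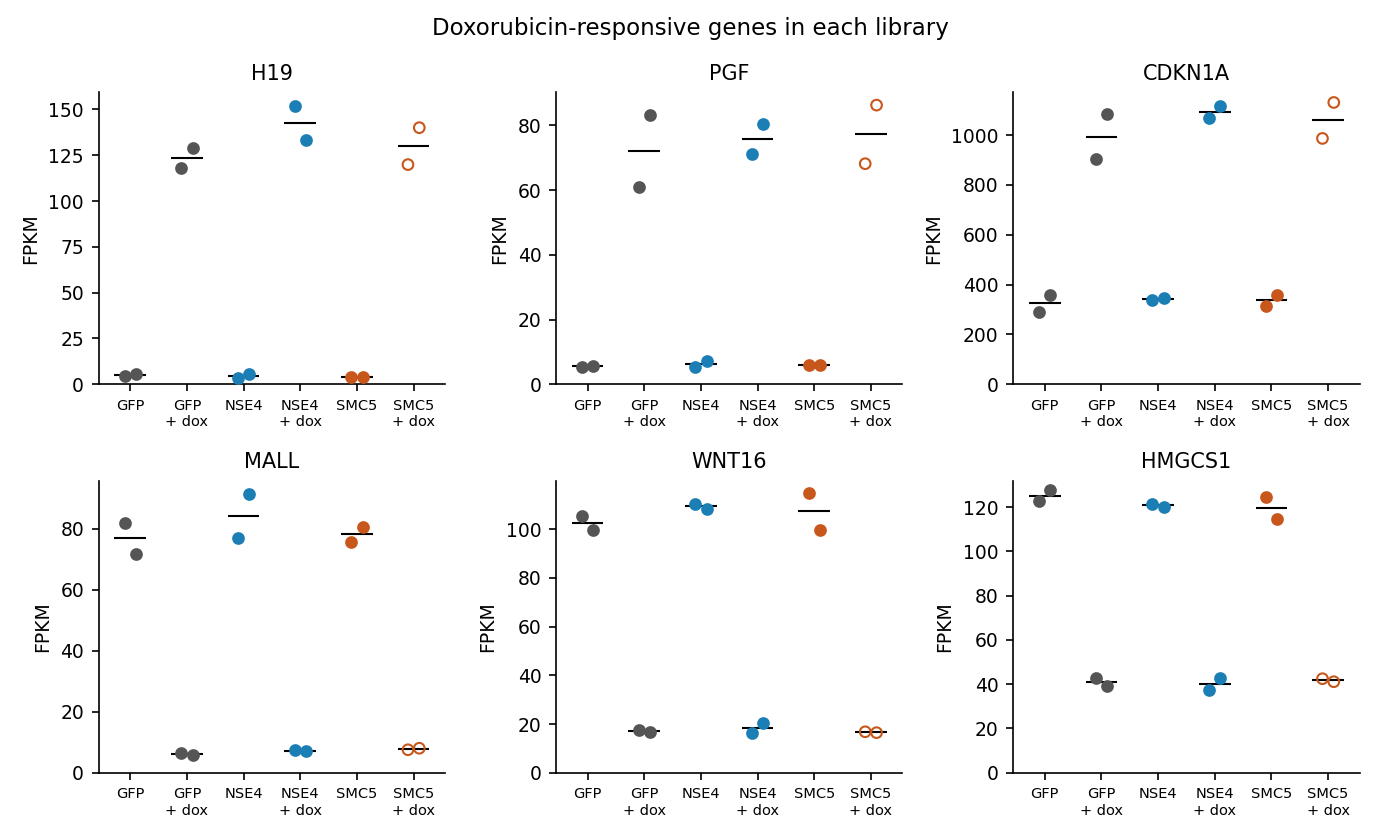
FPKM of H19, PGF, CDKN1A, MALL, WNT16 and HMGCS1 in each library (points) by group, with the mean of the 2 columns as a line and the 2 columns counted as 1 sample as open points. H19 went from 5.07 to 124 FPKM and MALL from 76.9 to 6.04 FPKM with doxorubicin in GFP cells.

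Among p53 targets in GFP cells, TIGAR, a fructose-bisphosphatase that slows glycolysis, rose from 7.48 ± 0.492 to 49.8 ± 1.55 FPKM (log2 change 2.58). SESN1, a stress-induced sestrin, rose from 5.95 ± 0.647 to 32.0 ± 0.984 FPKM, and PMAIP1, the BH3-only protein NOXA, from 52.1 ± 1.45 to 154 ± 7.99 FPKM. The locus AC025423.1,AC025423.2,MDM2, which holds a ubiquitin ligase gene of that list, rose from 73.4 ± 14.1 to 335 ± 26.8 FPKM (adjusted p = 1.10e-04). Over the p53 target list 27 loci rose and 1 fell, 28 and 1 adjusted over the list alone, with a median log2 change of 1.51. The list was called by camera (adjusted p = 9.63e-18). It was not called at adjusted p = 0.196 with an estimated correlation.

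Of 17 pro-apoptotic BCL2 family and caspase loci in GFP cells 11 rose and 0 fell with doxorubicin, 12 and 0 adjusted over the list alone. APAF1, the scaffold of the apoptosome, rose from 7.35 ± 0.0115 to 19.6 ± 0.370 FPKM. The list had a median log2 change of 0.54 and a camera adjusted p = 4.95e-04, against adjusted p = 0.722 with an estimated correlation. Of 6 anti-apoptotic loci 1 rose and 2 fell (camera adjusted p = 0.39). BCL2L1, the anti-apoptotic BCL-xL gene, fell from 77.5 ± 0.304 to 51.2 ± 5.99 FPKM, and BIRC3, an inhibitor of apoptosis that is also an NF-kB target, from 7.38 ± 0.575 to 2.45 ± 0.764 FPKM.

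Of 22 G1/S and DNA replication loci 8 rose and 0 fell, also adjusted over the list alone. PCNA, the sliding clamp of DNA polymerases and itself a p53 target, rose from 105 ± 7.15 to 488 ± 42.3 FPKM. CCNE2, a cyclin of S phase entry, rose from 4.36 ± 1.53 to 18.1 ± 1.81 FPKM, and RRM1, the large subunit of ribonucleotide reductase, from 25.9 ± 0.375 to 58.8 ± 9.75 FPKM. The list was called by camera at adjusted p = 0.0014, and not at adjusted p = 0.722 with an estimated correlation. Of 22 homologous recombination and Fanconi loci 12 rose and 1 fell, 13 and 1 adjusted over the list alone (camera adjusted p = 0.00566, adjusted p = 0.722 with an estimated correlation). RAD51C, a gene of recombination repair, rose from 44.8 ± 1.81 to 191 ± 12.03 FPKM. EXO1, an exonuclease of DNA end resection, went from 6.48 ± 2.15 to 14.1 ± 0.897 FPKM (adjusted p = 0.0123), a call lost without GFP replicate 2 (0.0779) or GFP replicate 2 with doxorubicin (0.0734).

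Cholesterol synthesis loci fell in 15 of 16 cases, also adjusted over the list alone, with a median log2 change of −1.29. HMGCS1, which makes HMG-CoA, fell from 125 ± 3.29 to 40.9 ± 2.58 FPKM. IDI1, an isomerase of the isoprenoid branch, fell from 108 ± 7.18 to 42.2 ± 2.94 FPKM, and DHCR7, the last reductase of the pathway, from 127 ± 7.47 to 45.9 ± 0.939 FPKM. The list was called by camera at adjusted p = 4.88e-11, and not at adjusted p = 0.316 with an estimated correlation. Of 15 immediate early loci 2 rose and 8 fell, 2 and 10 adjusted over the list alone (median −0.92, camera adjusted p = 0.00269, adjusted p = 0.722 with an estimated correlation). KLF4 and KLF6, Krüppel-like transcription factors, fell from 52.3 ± 7.80 to 22.7 ± 2.64 FPKM and from 62.0 ± 7.54 to 25.5 ± 2.14 FPKM, and MYC, the growth-promoting transcription factor, from 182 ± 14.5 to 113 ± 11.8 FPKM.

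**Figure D4:**
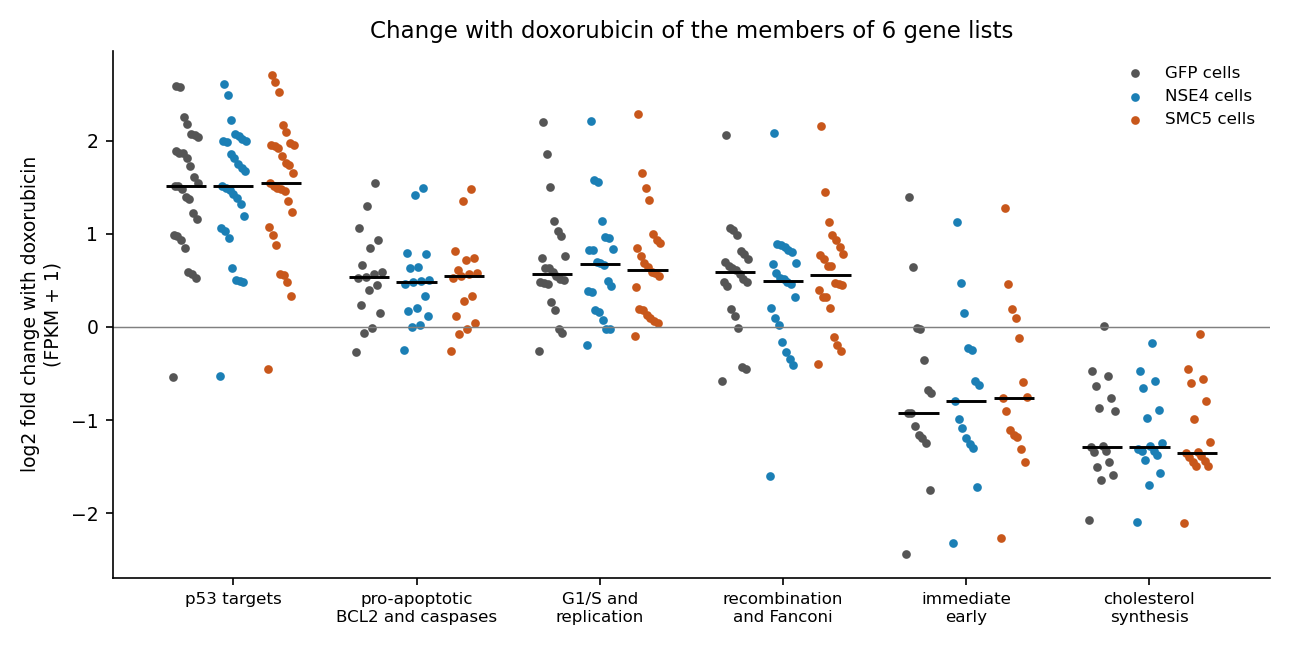
Log2 fold change with doxorubicin, on the log2(FPKM + 1) scale, of each tested locus (points) of 6 gene lists in GFP, NSE4 and SMC5 cells; the bar is the list's median. The median of the p53 target list in GFP cells was 1.51 and that of the cholesterol synthesis list −1.29.

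The remaining lists were not called by camera in GFP cells, and their members moved in opposite directions or mostly did not pass. Fry called some lists that camera did not. Interferon-stimulated and heat shock loci (adjusted p = 0.034 each) and antigen presentation and mesenchymal loci (0.0298 each) were called up. Anti-apoptotic (0.034), Wnt target (0.0118) and hepatocyte and neural loci (8.34e-04) were called down. The others did not pass fry. Of 23 G2/M and mitosis loci 2 rose and 7 fell, 4 and 9 adjusted over the list alone (camera adjusted p = 0.323). KIF20A, a mitotic kinesin, fell from 23.1 ± 0.583 to 11.04 ± 1.05 FPKM, and CDC20, an activator of the anaphase-promoting complex, from 113 ± 4.40 to 61.6 ± 6.53 FPKM. NUSAP1, a spindle-associated protein, went from 50.2 ± 0.528 to 81.5 ± 14.1 FPKM (adjusted p = 0.0116), a call lost without GFP replicate 1 (0.0601), GFP replicate 2 (0.0556) or GFP replicate 2 with doxorubicin (0.075). Of 17 cohesin and condensin loci 2 rose and 4 fell, 3 and 5 adjusted over the list alone (0.566). NCAPH2, a condensin II subunit, rose from 24.99 ± 0.04999 to 61.7 ± 12.01 FPKM, and STAG2, a cohesin subunit, fell from 34.6 ± 0.488 to 12.3 ± 1.75 FPKM (adjusted p = 0.0513 without GFP replicate 1 with doxorubicin). Of the 9 SMC5/6 complex and loader loci 1 rose and 1 fell (0.854). NSMCE3, a subunit that binds DNA beside the kleisin, was at 5.99 ± 0.0525 and 8.63 ± 0.0825 FPKM (adjusted p = 0.0189), a call lost with any 1 of the 4 libraries left out (0.0643 to 0.0797).

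NSMCE2, the SUMO ligase of the SMC5/6 complex, was at 16.4 ± 1.64 and 12.3 ± 0.936 FPKM in GFP cells without and with doxorubicin (adjusted p = 0.0329), a call lost without GFP replicate 1 (0.173) and without either doxorubicin-treated GFP library (0.0532 and 0.15). NSMCE1, its RING finger subunit (log2 change −0.25, adjusted p = 0.116), NSMCE4A (0.28, 0.154) and SMC5 (−0.55, 0.618) did not pass. The log2 difference of SMC5 turned to 0.36 without GFP replicate 1 and to 0.10 without GFP replicate 2 with doxorubicin.

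Of 25 interferon-stimulated loci in GFP cells 9 rose and 3 fell with doxorubicin, also adjusted over the list alone (camera adjusted p = 0.0859). OASL, an antiviral OAS-like protein, rose from 10.6 ± 1.22 to 27.8 ± 4.07 FPKM, HERC5, a ligase for ISG15, from 7.13 ± 0.205 to 13.9 ± 1.46 FPKM, IFNL1, a type III interferon, from 1.26 ± 0.132 to 4.59 ± 0.308 FPKM, and ISG15, a ubiquitin-like modifier, from 809 ± 102 to 1447 ± 31.3 FPKM. Of 10 antigen presentation loci 3 rose and 0 fell (0.102), among them TAP1, a peptide transporter, from 34.2 ± 1.66 to 77.2 ± 7.09 FPKM and the shared HLA-B,HLA-C locus from 1645 ± 279 to 3639 ± 9.31 FPKM. Of 13 NF-kB target loci 2 rose and 4 fell, 3 and 4 adjusted over the list alone (0.541). ICAM1, an adhesion molecule, rose from 1.22 ± 0.171 to 7.10 ± 1.91 FPKM. Of 12 heat shock loci 7 rose and 4 fell (0.4). HSPB1, the small heat shock protein HSP27, rose from 454 ± 5.23 to 1015 ± 111 FPKM, and HSP90AA1, the inducible HSP90 alpha, fell from 554 ± 13.1 to 330 ± 11.7 FPKM. Of 16 integrated stress response and UPR loci 2 rose and 4 fell (0.346), with CEBPB, a bZIP transcription factor, rising from 74.3 ± 8.32 to 146 ± 1.60 FPKM and ATF4, the effector of that response, falling from 249 ± 7.18 to 141 ± 11.6 FPKM.

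Of 10 Wnt target loci in GFP cells 2 rose and 6 fell, 2 and 7 adjusted over the list alone (camera adjusted p = 0.063). DKK1, a secreted Wnt inhibitor, fell from 413 ± 19.1 to 222 ± 8.24 FPKM and CCND1, cyclin D1, from 167 ± 1.16 to 122 ± 0.682 FPKM, and TCF7, a Wnt-responsive transcription factor, rose from 10.2 ± 0.508 to 18.0 ± 0.330 FPKM. Of 18 ribosome biogenesis loci 0 rose and 4 fell (0.249), among them NPM1, nucleophosmin, from 678 ± 7.61 to 397 ± 22.1 FPKM and FBL, the nucleolar methyltransferase fibrillarin, from 235 ± 7.77 to 163 ± 6.46 FPKM. Of 11 epithelial loci 3 rose and 3 fell (0.667), with KRT20, an intestinal keratin, rising from 0.961 ± 0.0273 to 5.29 ± 0.771 FPKM and CLDN3, a tight junction claudin, falling from 22.1 ± 1.74 to 9.66 ± 1.93 FPKM. Of 8 mesenchymal loci 2 rose and 1 fell, 3 and 1 adjusted over the list alone (0.533). ACTA2, smooth muscle actin and a p53-responsive gene in some cells, rose from 3.49 ± 0.355 to 17.3 ± 1.04 FPKM. Of 25 histone loci 3 rose and 3 fell (0.851). HIST1H4D, an H4 gene, was listed at 0 before and at 4.10 and 3.43 FPKM after doxorubicin. HIST1H3B, an H3 gene, was at 0.935 and 1.26 FPKM before and listed at 0 after (adjusted p = 0.0608 without GFP replicate 2). Of 9 non-homologous end joining loci 0 rose and 2 fell, 0 and 1 adjusted over the list alone (0.19). XRCC4, a scaffold of DNA ligase IV, was at 17.02 ± 1.38 and 11.7 ± 0.983 FPKM (adjusted p = 0.0141, but 0.0867 without GFP replicate 2 and 0.0749 without GFP replicate 1 with doxorubicin).

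Of 10 loci of mitochondrially encoded mRNAs in GFP cells 1 rose and 0 fell (camera adjusted p = 0.102). MT-ND1, a subunit of respiratory complex I, was at 2384 ± 389 and 3586 ± 463 FPKM (adjusted p = 0.0218, but 0.136 without GFP replicate 2 and 0.126 without GFP replicate 1 with doxorubicin). For the G2/M list the median was 0.01 with a mean of −0.09, for the histone list −0.05 with a mean of 0.04, and for the epithelial list −0.07 with a mean of 0.04, and camera's direction was down for each. Among markers of other cell types HBA1, a haemoglobin gene, rose from 1.26 ± 0.642 to 5.65 ± 0.0940 FPKM and LAPTM5, a lysosomal protein of leukocytes, from 0.132 ± 0.0235 to 1.43 ± 0.612 FPKM. COL1A1, a fibroblast collagen gene, was at 18.6 ± 1.11 and 21.5 ± 7.67 FPKM (log2 difference 0.16, adjusted p = 0.712, turning to −0.20 without GFP replicate 2 with doxorubicin). Of 4 hepatocyte and neural loci 0 rose and 2 fell, 2 and 2 adjusted over the list alone (camera adjusted p = 0.397). SYT1, a synaptic vesicle protein, fell from 13.2 ± 0.414 to 3.09 ± 0.0848 FPKM.

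In NSE4 cells doxorubicin again raised p53 targets and lowered cholesterol synthesis genes. H19 rose from 4.504 ± 1.31 to 143 ± 13.1 FPKM (SD, n = 2; log2 change 4.73, SE 0.17, adjusted p = 1.67e-05), CDKN1A from 341 ± 5.00 to 1093 ± 36.3 FPKM (1.68) and PGF from 6.27 ± 1.19 to 75.8 ± 6.55 FPKM (3.41). MALL fell from 84.2 ± 10.4 to 7.23 ± 0.219 FPKM (−3.37) and WNT16 from 109 ± 1.24 to 18.4 ± 2.81 FPKM (−2.51). In limma's test 2575 loci rose and 2205 fell, 792 and 441 of them at least 2-fold (6634 at an unadjusted p under 0.05). The comparison asks how cells with excess NSE4A respond to the drug. The count was 2437 when fitted on the 4 libraries compared alone, and 3064 without NSE4 replicate 1, 2974 without NSE4 replicate 1 with doxorubicin and 2920 without NSE4 replicate 2 with doxorubicin. Falls outnumbered rises under quantile normalization (2574 rose, 2715 fell), without NSE4 replicate 1 (1442 and 1622) and without NSE4 replicate 2 with doxorubicin (1373 and 1547).

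AKR1B10 rose in NSE4 cells from 0.479 ± 0.151 to 15.2 ± 1.30 FPKM and CDIP1 from 4.72 ± 0.770 to 47.3 ± 6.10 FPKM. GALR2, a galanin receptor, rose from 0.263 ± 0.0392 to 9.94 ± 1.98 FPKM, GAST, the hormone gastrin, from 1.36 ± 0.249 to 17.7 ± 1.15 FPKM, and S100A2, a calcium-binding protein, from 27.2 ± 9.33 to 215 ± 4.66 FPKM. LCE1F, a cornified envelope protein gene, was listed at 0 before and at 6.68 and 7.001 FPKM after doxorubicin (adjusted p = 1.32e-04). AL021707.8 (listed at 0, then 234 and 91.4 FPKM, adjusted p = 0.0192) did not pass with any 1 of the 4 libraries left out (0.0659 to 0.108). LINC01952 (listed at 0, then 2.12 and 61.1 FPKM, 0.0395) did not pass without NSE4 replicate 1 (0.131), NSE4 replicate 2 (0.124) or NSE4 replicate 2 with doxorubicin (0.12). FHIT, a hydrolase gene at a fragile site, was at 56.2 and 34.0 FPKM before and 6.02 and 0.268 FPKM after doxorubicin (adjusted p = 0.0381, but 0.155 without NSE4 replicate 1, 0.0942 without NSE4 replicate 2 and 0.219 without NSE4 replicate 2 with doxorubicin). PDSS2 (51.2 and 17.4 FPKM before, 5.14 and 4.07 after, 0.0323) lost its call without NSE4 replicate 1 (0.181) and without either doxorubicin-treated NSE4 library (0.105 and 0.136).

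Listed at 0 in NSE4 cells after doxorubicin were the loci AC005899.3 (18.6 and 4.06 FPKM before), AC243773.3 (8.31 and 5.74), RN7SL9P (3.50 and 5.58), RN7SL208P (8.23 and 9.79), AC009994.1 (9.28 and 6.51) and SRP68P3 (6.09 and 3.55). RN7SL208P did not pass without either doxorubicin-treated NSE4 library (adjusted p = 0.0544 and 0.0547), and AC009994.1 with any 1 of the 4 libraries left out (0.0863 to 0.132). SRP68P3 did not pass without NSE4 replicate 1 (0.0883) or either doxorubicin-treated NSE4 library (0.0715 each).

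Of 29 p53 target loci in NSE4 cells 25 rose and 1 fell, 27 and 1 adjusted over the list alone (median log2 change 1.51, camera adjusted p = 7.89e-18, adjusted p = 0.194 with an estimated correlation). TIGAR rose from 7.09 ± 0.759 to 48.5 ± 3.97 FPKM, PMAIP1 from 53.8 ± 0.899 to 154 ± 1.78 FPKM and the MDM2 locus (AC025423.1,AC025423.2,MDM2) from 78.1 ± 11.9 to 367 ± 38.6 FPKM. Of 17 pro-apoptotic loci 8 rose and 0 fell, 10 and 0 adjusted over the list alone (camera adjusted p = 0.00171, adjusted p = 0.738 with an estimated correlation), including APAF1 from 6.80 ± 0.427 to 19.8 ± 0.00240 FPKM. Of 22 G1/S loci 9 rose and 0 fell, also adjusted over the list alone (0.00243, adjusted p = 0.738 with an estimated correlation), with PCNA going from 107 ± 37.7 to 487 ± 23.5 FPKM. Of 22 recombination and Fanconi loci 8 rose and 0 fell, 9 and 0 adjusted over the list alone (0.0349, adjusted p = 0.738 with an estimated correlation), with RAD51C going from 47.7 ± 5.88 to 204 ± 6.14 FPKM.

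Of 16 cholesterol synthesis loci in NSE4 cells 15 fell, also adjusted over the list alone (camera adjusted p = 4.42e-12, adjusted p = 0.267 with an estimated correlation), including HMGCS1 from 121 ± 0.908 to 40.2 ± 3.89 FPKM and IDI1 from 110 ± 0.390 to 42.0 ± 1.67 FPKM. Of 15 immediate early loci 0 rose and 8 fell, 2 and 9 adjusted over the list alone (0.00265, adjusted p = 0.738 with an estimated correlation). KLF4 fell from 61.0 ± 3.28 to 25.1 ± 3.12 FPKM, KLF6 from 73.5 ± 8.97 to 29.5 ± 5.95 FPKM and FOS from 275 ± 130 to 51.4 ± 10.7 FPKM. No other list was called by camera. In the SMC5/6 list NSMCE4A was at 4128 ± 82.1 and 5785 ± 710 FPKM (log2 change 0.48, adjusted p = 0.031), a call lost without NSE4 replicate 1 (0.116), NSE4 replicate 2 (0.0875) or NSE4 replicate 2 with doxorubicin (0.172). NSMCE3 (5.66 ± 0.383 and 7.93 ± 0.194 FPKM, 0.0272) and NSMCE1 (48.8 ± 1.04 and 38.3 ± 0.144 FPKM, 0.0434) passed, but not with any 1 of the 4 libraries left out (0.057 to 0.113 and 0.0985 to 0.142). SMC5 did not pass (log2 difference 0.30, adjusted p = 0.8, turning to −0.12 without NSE4 replicate 1 and to −0.64 without NSE4 replicate 2 with doxorubicin).

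In SMC5 cells p53 targets rose and cholesterol synthesis genes fell with doxorubicin as well, here against a single doxorubicin-treated sample. H19 rose from 3.84 ± 0.0621 to 130.0 FPKM (log2 change 4.76, SE 0.21, adjusted p = 4.12e-05), CDKN1A from 337 ± 31.8 to 1059 FPKM (1.65) and PGF from 6.07 ± 0.00460 to 77.2 FPKM (3.47). MALL fell from 78.2 ± 3.43 to 7.79 FPKM (−3.17) and WNT16 from 107 ± 10.8 to 16.6 FPKM (−2.62). NR2F1, an orphan nuclear receptor, fell from 58.5 ± 1.90 to 9.09 FPKM (−2.56). In limma's test 1747 loci rose and 1563 fell, 794 and 453 of them at least 2-fold (5590 at an unadjusted p under 0.05). Fitted on the 3 samples compared alone, limma called 0 loci, the fit with the 12 columns called 6077, and the count was 1766 without SMC5 replicate 1 and 1963 without SMC5 replicate 2. Falls outnumbered rises under quantile normalization (1922 rose, 1957 fell), at a minimum FPKM of 5 (1455 and 1489), without SMC5 replicate 1 (867 and 899) and without SMC5 replicate 2 with doxorubicin (1573 and 1695). The spread of the lone sample was taken to be that of the other groups.

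GAST rose in SMC5 cells from 0.772 ± 0.665 to 18.8 FPKM and GALR2 from 0.363 ± 0.223 to 12.02 FPKM. Listed at 0 before doxorubicin were SNORD91A (217 and 211 FPKM in the 2 columns after) and AC032044.2 (68.3 and 69.6). AC011445.2 (473 and 522), AC007136.1 (70.8 and 73.5) and AC087362.2 (8.56 and 10.1) were also listed at 0 before, but did not pass without SMC5 replicate 1 (adjusted p = 0.0914, 0.0915 and 0.0656) or SMC5 replicate 2 (0.0869, 0.0871 and 0.0625). AL355512.1 went from 2.00 ± 0.513 to 51.2 FPKM (0.125 without SMC5 replicate 1 and 0.0977 without SMC5 replicate 2). Listed at 0 in the treated sample were AC092567.1 (35.6 and 13.8 FPKM before), AC005899.3 (38.1 and 10.1), AC098934.3 (74.1 and 80.1), AC009994.1 (8.13 and 24.7), RN7SL368P (12.04 and 6.96), AC092651.1 (4.27 and 11.1) and AC113189.1 (3.13 and 8.51). Without SMC5 replicate 1 AC098934.3 (0.116), AC009994.1 (0.0578) and RN7SL368P (0.118) did not pass. Without SMC5 replicate 2 these loci (0.114, 0.143 and 0.0652), AC092651.1 (0.108) and AC113189.1 (0.0513) did not pass.

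Of 29 p53 target loci in SMC5 cells 24 rose and 0 fell, 26 and 1 adjusted over the list alone (median log2 change 1.55, camera adjusted p = 2.77e-19, adjusted p = 0.165 with an estimated correlation). TIGAR rose from 7.21 ± 0.370 to 49.8 FPKM, PMAIP1 from 52.9 ± 2.48 to 150.1 FPKM and the MDM2 locus (AC025423.1,AC025423.2,MDM2) from 64.0 ± 9.66 to 372 FPKM. Of 17 pro-apoptotic loci 6 rose and 0 fell, 11 and 0 adjusted over the list alone (0.00161, adjusted p = 0.707 with an estimated correlation), including APAF1 from 8.84 ± 0.0160 to 24.2 FPKM. Of 22 G1/S loci 5 rose and 0 fell, 7 and 0 adjusted over the list alone (0.00198, adjusted p = 0.707 with an estimated correlation), with PCNA going from 98.4 ± 2.67 to 486 FPKM. Of 22 recombination and Fanconi loci 6 rose and 0 fell, 8 and 0 adjusted over the list alone (0.00289, adjusted p = 0.707 with an estimated correlation), with RAD51C going from 43.4 ± 0.477 to 198 FPKM.

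Of 16 cholesterol synthesis loci in SMC5 cells 14 fell, 15 adjusted over the list alone (camera adjusted p = 5.36e-12, adjusted p = 0.271 with an estimated correlation), including HMGCS1 from 120 ± 6.99 to 41.8 FPKM and IDI1 from 110 ± 3.24 to 39.9 FPKM. Of 15 immediate early loci 0 rose and 6 fell, 1 and 7 adjusted over the list alone (0.00655, adjusted p = 0.707 with an estimated correlation). KLF4 fell from 60.4 ± 1.68 to 23.8 FPKM, KLF6 from 70.9 ± 7.40 to 30.6 FPKM and FOS from 243 ± 30.4 to 49.6 FPKM (adjusted p = 0.0116, but 0.0528 without SMC5 replicate 2). No other list was called by camera. Within the SMC5/6 list NSMCE1 was at 47.6 ± 6.80 and 31.7 FPKM (0.0196, but 0.0642 without SMC5 replicate 2) and NSMCE2 at 17.9 ± 0.562 and 11.5 FPKM (0.0193, but 0.0571 without SMC5 replicate 1 and 0.0718 without SMC5 replicate 2). SMC5 (log2 difference −0.19, adjusted p = 0.914) and NSMCE4A (0.00, adjusted p = 1, turning to −0.19 without SMC5 replicate 2) did not pass.

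The drug responses of the 3 backgrounds were alike in direction. Of the loci called in GFP and NSE4 cells 3799 were shared, 3796 of them in the same direction, and GFP and SMC5 cells shared 2918, of which 2915 had the same direction. In all 3 backgrounds 1460 loci rose and 1306 fell. Across the 15833 loci, which are not independent replicates, log2 changes in GFP and NSE4 cells had a Pearson r of 0.749, and those in GFP and SMC5 cells 0.711.

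**Figure D5:**
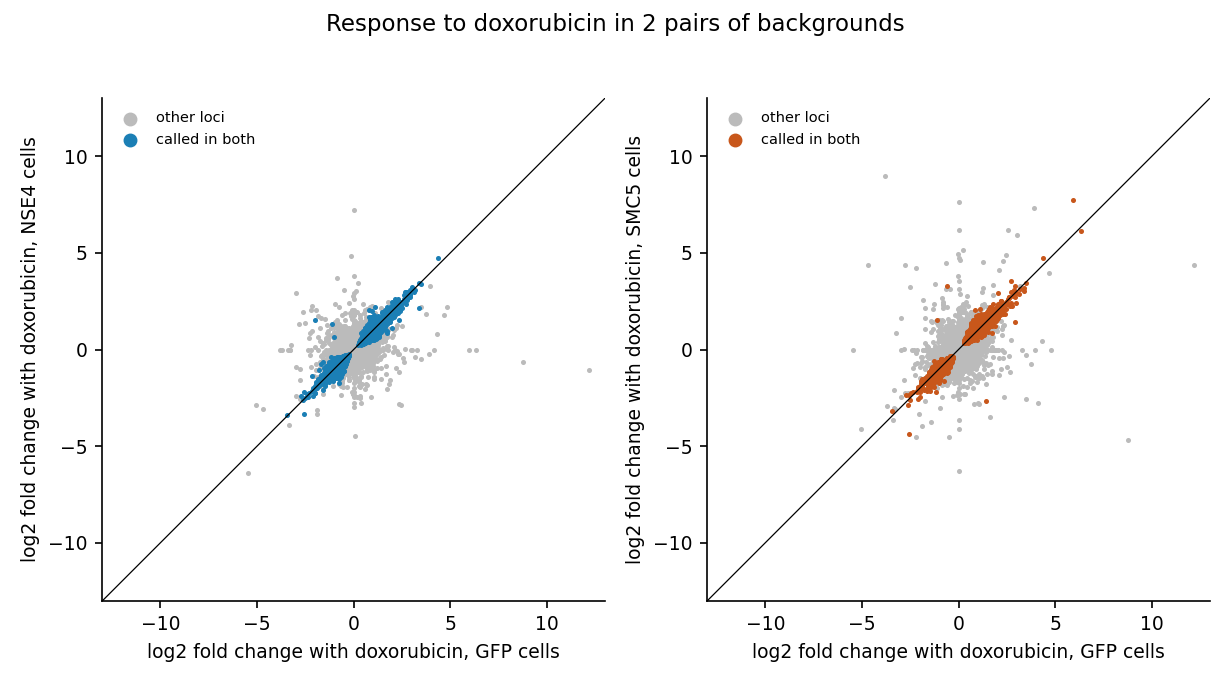
Log2 fold change with doxorubicin of each tested locus (points) in GFP cells (horizontal) against NSE4 cells (left, vertical) or SMC5 cells (right, vertical), both on the log2(FPKM + 1) scale; coloured points are called in both backgrounds and the line marks equal change. Of the coloured loci 3796 of 3799 and 2915 of 2918 moved in the same direction.

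The NSE4A plasmid without doxorubicin raised its own gene, and few other loci were called. Beside NSMCE4A, limma called 5 loci higher and 1 lower than in GFP cells, with 452 loci at an unadjusted p under 0.05 where 792 would be expected by chance. With a count below 792 the p-values may be too large, so changes may have been missed. A replicate block gave 5 calls, 4 of them shared with the 7 calls that include NSMCE4A. With NSMCE4A the 6 higher and 1 lower became 4 and 6 without GFP replicate 1, 5 and 5 without GFP replicate 2, 11 and 1 without NSE4 replicate 1, and 12 and 0 without NSE4 replicate 2, so their balance depends on the libraries used. AC010761.6 was listed at 0 in GFP cells and at 226 and 51.3 FPKM in NSE4 cells, and AC243773.3 at 0 and at 8.31 and 5.74 FPKM. RN7SL472P (4.52 and 3.67 FPKM) and AC110792.4 (3.25 and 2.29 FPKM) were also listed at 0 in GFP cells, and RPL37AP8 was at 5.52 and 3.18 FPKM there and listed at 0 in NSE4 cells. AF228730.6, an unprocessed pseudogene, was at 0.954 ± 0.00559 and 24.4 ± 6.66 FPKM (adjusted p = 0.0445). AF228730.6 and AC110792.4 did not pass with any 1 of the 4 libraries left out (0.115 to 0.277 and 0.0572 to 0.198). RPL37AP8 did not pass without GFP replicate 1 (0.0998), NSE4 replicate 1 (0.107) or NSE4 replicate 2 (0.106), nor RN7SL472P without NSE4 replicate 1 (0.0541). SMC5 did not pass (log2 difference −0.29, adjusted p = 1, turning to 0.62 without GFP replicate 1 and to 0.13 without NSE4 replicate 1).

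Interferon-stimulated loci lay slightly higher in NSE4 cells than in GFP cells, with a median log2 difference of 0.20 (0.305 without NSE4 replicate 1, 0.136 without NSE4 replicate 2), but 0 of 25 passed over all loci and 1 adjusted over the list alone. Camera called the list (adjusted p = 1.4e-08), which it did not at adjusted p = 0.455 with an estimated correlation. IFNL1 was at 1.26 ± 0.132 FPKM in GFP cells and 3.28 ± 0.296 FPKM in NSE4 cells (adjusted p = 0.663), and IFI6, an interferon-induced mitochondrial protein, at 1010 ± 133 and 1307 ± 7.62 FPKM (adjusted p = 1). Camera also called immediate early loci (median 0.23, 0 of 15 passed, adjusted p = 0.00999, adjusted p = 0.974 with an estimated correlation) and mitochondrially encoded mRNAs (median 0.15, or −0.04 under quantile normalization, 0 of 10 passed, adjusted p = 0.0185, adjusted p = 0.974 with an estimated correlation). The SMC5/6 list, which holds the plasmid gene, had 1 of 9 loci higher, a median of −0.01 and a mean of 0.63 (adjusted p = 0.0354, adjusted p = 0.455 with an estimated correlation). The p53 target list (median 0.07, 0 of 29 passed, camera adjusted p = 0.309) and the pro-apoptotic list (0.05, 0 of 17, 0.525) were not called.

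The SMC5 plasmid without doxorubicin gave no call. In limma's test 0 loci were called between SMC5 and GFP cells, with 489 at an unadjusted p under 0.05 where 792 would be expected. Every comparison of plasmids and both interactions stayed below 792 (406 to 534), so these p-values may be too large. The lack of calls therefore does not show that the plasmid had no effect, and SMC5 itself did not pass. NSMCE4A was lower, at 37.8 ± 7.43 FPKM against 71.8 ± 4.31 FPKM in GFP cells (log2 difference −0.92, SE 0.14), and did not pass over all loci (adjusted p = 0.426), although it did adjusted over the list alone. Interferon-stimulated loci had a median log2 difference of 0.27, with 0 of 25 passing over all loci and 6 adjusted over the list alone (camera adjusted p = 1.26e-12, adjusted p = 0.462 with an estimated correlation). IFNL1 was at 3.12 ± 0.849 FPKM and IFI6 at 1356 ± 72.4 FPKM in SMC5 cells (adjusted p = 1 each). The p53 target (median 0.03, camera adjusted p = 0.647) and pro-apoptotic lists (0.02, 0.237) were not called. Leaving out 1 library gave 1 locus higher and 4 lower without GFP replicate 2, 1 and 6 without GFP replicate 1, 7 and 0 without SMC5 replicate 1, and 9 and 2 without SMC5 replicate 2.

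With doxorubicin, few loci beside NSMCE4A were again called between NSE4 and GFP cells. Higher in NSE4 cells were AC010761.6 (53.7 and 43.8 FPKM, listed at 0 in GFP cells), RN7SL280P (3.24 and 2.87) and AC110792.4 (3.09 and 2.42), and in limma's test 4 loci were higher, NSMCE4A among them, and 5 lower (534 at an unadjusted p under 0.05). There were 1 higher and 8 lower without GFP replicate 1 with doxorubicin, 3 and 9 without GFP replicate 2 with doxorubicin, 6 and 5 without NSE4 replicate 1 with doxorubicin, and 11 and 4 without NSE4 replicate 2 with doxorubicin. With no filter on low values there were 59 and 41. Listed at 0 in NSE4 cells were AC032044.2 (89.1 and 70.6 FPKM in GFP cells), SNORD91A (69.2 and 53.3), AC073107.2 (9.64 and 7.75) and AC068580.1 (5.45 and 8.77). ZWILCH, a kinetochore protein of the mitotic checkpoint, was at 19.3 ± 1.33 FPKM in GFP cells and 8.99 ± 0.205 FPKM in NSE4 cells after doxorubicin (log2 difference −1.02, SE 0.12, adjusted p = 0.047), against 7.40 ± 0.816 and 8.42 ± 0.394 FPKM without it. It did not pass with any 1 of the 4 libraries left out (0.151 to 0.226), nor did AC010761.6 (0.0913 to 0.13) or AC110792.4 (0.0624 to 0.13), and RN7SL280P did not without GFP replicate 1 with doxorubicin (0.0518) or NSE4 replicate 1 with doxorubicin (0.0677). SMC5 did not pass (0.56, adjusted p = 1, turning to −0.09 without GFP replicate 2 with doxorubicin and to −0.38 without NSE4 replicate 2 with doxorubicin).

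Between doxorubicin-treated NSE4 and GFP cells, interferon-stimulated loci had a median log2 difference of 0.18 (0 of 25 passed, camera adjusted p = 1.32e-04, adjusted p = 0.756 with an estimated correlation). That median was 0.092 without GFP replicate 1 with doxorubicin (camera adjusted p = 0.0146), 0.289 without GFP replicate 2 with doxorubicin, 0.107 without NSE4 replicate 2 with doxorubicin (0.0176) and 0.231 without NSE4 replicate 1 with doxorubicin. Immediate early loci had a median of 0.19 (0 of 15 passed, 0.0126, adjusted p = 0.964 with an estimated correlation). G2/M loci had a median of −0.09 (0 of 23 passed, 1.88e-04, adjusted p = 0.894 with an estimated correlation). The SMC5/6 list was called with the plasmid gene in it (1 of 9 passed, 0.0193, adjusted p = 0.655 with an estimated correlation). The pro-apoptotic list was not called (median −0.01, camera adjusted p = 0.744), nor was the p53 target list (0.07, 0.251).

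With doxorubicin, SMC5 cells differed from GFP cells at 5 called loci, 4 higher and 1 lower (limma, 476 at an unadjusted p under 0.05), none of which is named by a single protein-coding gene. The SMC5 side is 1 sample whose spread is taken from the other groups, and the fit on the 3 samples compared alone called 0 loci. Without GFP replicate 1 with doxorubicin the count was 10, with 6 higher and 4 lower. SVIL-AS1, annotated as a transcribed pseudogene, was at 7.91 ± 1.16 FPKM in GFP cells and 125 FPKM in SMC5 cells (log2 difference 3.83, adjusted p = 1.38e-04) at 1 of 3 tested loci of that name. The AL360181.1,BANF1P2 locus was at 1.41 ± 0.256 and 68.0 FPKM (4.84, 1.38e-04) and the AC011471.1,RFX2 locus at 8.10 ± 1.05 and 51.3 FPKM (2.53, 0.0488). SNORD91A was at 61.3 ± 11.2 and 214 FPKM (1.80, 0.0349), and AC073107.2 was at 9.64 and 7.75 FPKM in GFP cells and listed at 0 in SMC5 cells. NSMCE4A was at 87.5 ± 2.60 and 37.5 FPKM (−1.20, SE 0.17, adjusted p = 0.167) and passed adjusted over the list alone. Interferon-stimulated loci had a median of 0.16 (0 of 25 passed, camera adjusted p = 5.25e-04, adjusted p = 0.984 with an estimated correlation). That median was 0.088 without GFP replicate 1 with doxorubicin (camera adjusted p = 0.0354) and 0.272 without GFP replicate 2 with doxorubicin. The p53 target (0.05, 0.519) and pro-apoptotic lists (−0.01, 0.907) were not called. The RFX2 locus did not pass without GFP replicate 1 with doxorubicin (0.142), GFP replicate 2 with doxorubicin (0.376) or SMC5 replicate 2 with doxorubicin (0.0654), nor SNORD91A without GFP replicate 2 with doxorubicin (0.159).

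Whether either plasmid changed the response to doxorubicin was tested as an interaction. In limma's test the log2 change with doxorubicin was higher in NSE4 than in GFP cells for 0 loci and lower for 5 (454 at an unadjusted p under 0.05), and in SMC5 cells higher for 2 and lower for 1 (440). Leaving out 1 library moved both counts and their balance. For NSE4 there were 2 higher and 3 lower without GFP replicate 1, 3 and 3 without GFP replicate 2, 1 and 7 without GFP replicate 1 with doxorubicin, 1 and 9 without NSE4 replicate 1, and 0 and 12 without NSE4 replicate 2, and with no filter on low values 41 and 30. For SMC5 there were 11 higher and 2 lower without GFP replicate 1, 9 and 1 without GFP replicate 2, 5 and 3 without SMC5 replicate 1, and 3 and 5 without SMC5 replicate 2, and with no filter 400 and 31. With all libraries the 5 were AC032044.2, SNORD91A, AC073107.2 and AC068580.1, listed at 0 in NSE4 cells with and without doxorubicin, and AC243773.3, listed at 0 in GFP cells with and without it and in NSE4 cells after it. The 3 were SVIL-AS1 (log2 difference 3.91, adjusted p = 9.34e-04), the AL360181.1,BANF1P2 locus (4.95, 9.34e-04) and AC073107.2 (−3.27, 0.0204), the last lost without GFP replicate 1 with doxorubicin (0.0536). AC243773.3 and AC068580.1 lost their calls without either GFP library (0.0964 to 0.133), without NSE4 replicate 1 (0.0667 and 0.0864) and without either doxorubicin-treated NSE4 library (0.0904 to 0.131), AC243773.3 also without either doxorubicin-treated GFP library (0.0692 and 0.0784), and AC068580.1 also without NSE4 replicate 2 (0.0894) and GFP replicate 2 with doxorubicin (0.0653). No list was called. For NSE4 the median interaction was 0.01 over p53 targets (camera adjusted p = 0.989) and −0.05 over pro-apoptotic loci (0.756), and for SMC5 it was 0.05 (0.883) and −0.01 (0.883). NSMCE4A (0.20 and −0.28) and SMC5 (0.85 and 0.36) did not pass (adjusted p = 1 each), and the sign for SMC5 turned without GFP replicate 1 (−0.06 and −0.55), for NSE4 cells without NSE4 replicate 2 with doxorubicin (−0.09) and for SMC5 cells without GFP replicate 2 with doxorubicin (−0.29). In simulated data of the same spread, 51% of 2-fold and 85% of 4-fold interactions were recovered for NSE4 and 35% and 91% for SMC5. The changed loci there had a mean of at least 5 FPKM, so recovery at lower FPKM is not known.

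NSE4 and SMC5 cells were also compared directly. Without doxorubicin NSMCE4A was higher in NSE4 cells by 6.75 on the log2 scale (adjusted p = 2.7e-07), as were the 5 loci AC010761.6, AF228730.6, AC243773.3, RN7SL472P and AC110792.4, so that 6 loci were higher and 0 lower (limma, 406 at an unadjusted p under 0.05). Fitted on the 4 libraries compared alone, 1 locus was higher and 6 lower, and 1 of the 6 calls above was shared. Without SMC5 replicate 1 there were 6 higher and 9 lower, without SMC5 replicate 2 4 higher and 10 lower, without NSE4 replicate 1 10 and 1, and without NSE4 replicate 2 14 and 2, so the direction of this small count depends on the libraries used. SMC5 differed by −5.95 (adjusted p = 0.0817). AF228730.6 (0.094 to 0.24) passed with none of the 4 libraries left out, AC110792.4 did not without NSE4 replicate 1 (0.183), SMC5 replicate 1 (0.136) or SMC5 replicate 2 (0.115), and RN7SL472P did not without NSE4 replicate 1 (0.0541). Camera called 4 lists with 0 members passing. G2/M loci had a median of −0.08 (adjusted p = 0.0138) and histone loci of −0.15 (0.0194), both lower in NSE4 cells. Recombination and Fanconi loci had a median of 0.15 (0.01) and mitochondrially encoded mRNAs of 0.17 (0.0135), or 0.00 under quantile normalization. Each had an adjusted p = 0.984 with an estimated correlation.

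With doxorubicin NSMCE4A differed between NSE4 and SMC5 cells by 7.22 (adjusted p = 5.33e-07), and 3 loci were higher and 6 lower in NSE4 cells (limma, 432 at an unadjusted p under 0.05). As above, the SMC5 side is 1 sample, and the fit on the 3 samples compared alone called 0 loci. Without NSE4 replicate 1 with doxorubicin there were 4 higher and 4 lower, without NSE4 replicate 2 with doxorubicin 6 and 6, and without SMC5 replicate 2 with doxorubicin 1 and 4. AC010761.6 and RN7SL280P were the others higher. Lower were AC032044.2 and SNORD91A, SVIL-AS1 (−3.52, adjusted p = 1.09e-04), the AL360181.1,BANF1P2 locus (−4.85), the AC011471.1,RFX2 locus (−2.38, 0.0474) and AC068580.1. SMC5 differed by −5.46 (adjusted p = 0.301). AC010761.6, RN7SL280P, AC068580.1 and the RFX2 locus did not pass without NSE4 replicate 1 with doxorubicin (0.152 to 0.22), NSE4 replicate 2 with doxorubicin (0.109 to 0.251) or SMC5 replicate 2 with doxorubicin (0.0532 to 0.0574). No list was called.

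The effects of the 2 plasmids were compared for overlap, since both were measured against the same GFP libraries. Without doxorubicin 0 loci were called in both, and 28 were shared at an unadjusted p under 0.01, against a mean of 26.3 in 100 simulations of unchanged groups that shared those controls. At that limma threshold 67 loci were higher and 44 lower for NSE4, and 60 and 40 for SMC5. The simulated counts per plasmid were not kept. The closeness of 28 and 26.3 therefore does not settle whether the overlap exceeds that of shared controls. With doxorubicin AC073107.2 was called lower in both and 14 loci were shared at the looser threshold, against 20.6 in the simulations. Independent lists would share 0.25 higher and 0.11 lower loci without doxorubicin, and 0.36 and 0.08 with it. Log2 differences across loci had a Pearson r of 0.456 without doxorubicin (simulated 0.501) and 0.38 with it (0.407), with covariances of 0.0465 (0.0393) and 0.049 (0.0389). With 2 GFP libraries per treatment the controls could be split only into single libraries, which was not done here, so part of any excess may come from them.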

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

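The interaction tests below were planned, and the check with GC-adjusted values was added after the data were seen. A difference between backgrounds in the response to doxorubicin was tested locus by locus with limma, and the loci that passed were singled out because the effect of the same drug differs between 2 transfected populations. For NSE4 against GFP cells 5 loci passed: AC032044.2 (fitted difference −6.328), SNORD91A (−5.949), AC073107.2 (−3.271), AC243773.3 (−2.985) and AC068580.1 (−2.989). Each is listed at 0 in every library of at least 3 of the 4 groups of this test, so its fitted value depends on the pseudocount and is no bound. AC032044.2 and SNORD91A were above 0 in the same groups, doxorubicin-treated GFP and SMC5 cells, so they may not be 2 separate results. Leaving out 1 library gave 4 to 12 loci here, with 0 to 3 of them higher, and 3 to 13 in the test of SMC5.

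For SMC5 against GFP cells 3 loci passed: the AL360181.1,BANF1P2 locus (4.949), SVIL-AS1 (3.908) and AC073107.2 (−3.271). SVIL-AS1 and the BANF1P2 locus are high in the 2 columns of doxorubicin-treated SMC5 cells that count as 1 sample, so their difference rests on a single sample. AC073107.2 is above 0 in the 2 doxorubicin-treated GFP libraries and in no other library, which gives it the same fitted value in both interactions. In the interaction of SMC5 it did not pass with a replicate block, with GC-adjusted values, at pseudocount 0.1 or at a minimum FPKM of 5. Where the annotation gives a type, these loci are noncoding transcripts or pseudogenes (AC243773.3 and the BANF1P2 locus have none), and CDKN1A and PMAIP1, the p53 and cell death genes of the report, are not on them. No biological explanation of these differences was tested.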

How the results depend on the processing

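Tests on 12 columns, protein-coding loci, GC-adjusted values, loci above 0 in every sample, list loci of 1 gene and list medians under the scalings were chosen after the results were seen. In every leave-one-out fit that leaves 1 sample in a group, that sample is assumed to vary like the other groups. Ranges that include fits without 1 of the merged doxorubicin-treated SMC5 columns are in that part no test of losing a sample.

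The counts for doxorubicin held within 1.5 times under both scalings, both filters and the other pseudocount, and fell when fewer samples gave the spread. For doxorubicin in GFP cells (4919) the fit on the groups compared gave 3168, the fold threshold 1259 and leaving out 1 library 2936 to 3516. For NSE4 cells (4780) these were 2437, 1233 and 2920 to 3569. For SMC5 cells (3310) they were 0, 1247 and 1766 to 3523, and 12 columns gave 6077. These totals hide a change of balance: under quantile normalization falls outnumbered rises in GFP, NSE4 and SMC5 cells, as they did without some of the libraries. Replicate numbers were checked for pairing by correlating replicate differences between groups. For the 10 pairs of groups with 2 libraries Pearson r was −0.039 to 0.074 and Spearman rho −0.004 to 0.192, and the 5 pairs with the merged doxorubicin-treated SMC5 columns gave r of 0.16 to 0.227 and rho of 0.293 to 0.445. Since not every pair exceeded 0.1 by either measure, the numbers were not used as a block in the reported fit. Over 10 FPKM the ratio of replicate 1 to replicate 2 still fell with GC content in every group (Spearman rho −0.307 to −0.859). Median-of-ratios size factors were 0.966 to 0.9835 in replicate 1 and 1.0133 to 1.0434 in replicate 2 of the unmerged groups. The reported fit leaves this shift in the spread. A replicate block gave 5913, 5809 and 4380. Of the 4919 loci in GFP cells 4918 were also called with 12 columns and 4814 with median-of-ratios scaling.

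Small counts moved by more. NSE4 without doxorubicin (7) had 11 loci with no filter, 2 at a minimum FPKM of 5, 3 at pseudocount 0.1, 1 on the groups compared, 1 among protein-coding loci, 2 above 0 in every sample and 10 to 12 leaving out 1 library. SMC5 without doxorubicin (0) had 9 with no filter, 1 on the groups compared, 2 with 12 columns and 5 to 11. NSE4 with doxorubicin (9) had 100 with no filter, 5 at pseudocount 0.1, 5 on the groups compared, 23 with 12 columns, 4 protein-coding, 1 above 0 in every sample and 9 to 15. SMC5 with doxorubicin (5) had 3 with median-of-ratios scaling, 539 with no filter, 2 at a minimum FPKM of 5, 2 at pseudocount 0.1, 3 with a replicate block, 0 on the groups compared, 129 with 12 columns, 0 protein-coding, 3 GC-adjusted and 4 to 10. The balance of higher and lower loci also changed without 1 library, for NSE4 without doxorubicin from 12 and 0 to 4 and 6 and for NSE4 with doxorubicin from 11 and 4 to 1 and 8, and the cause was not tested. The cause of the high counts with no filter was not tested.

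The interaction of NSE4 (5) had 71 with no filter, 2 at a minimum FPKM of 5, 2 at pseudocount 0.1, 3 with a replicate block, 8 on the groups compared, 9 with 12 columns, 0 protein-coding, 3 GC-adjusted, 0 above 0 in every sample and 4 to 12, from 3 higher and 3 lower to 0 and 12. The interaction of SMC5 (3) had 431 with no filter, 1 at a minimum FPKM of 5, 11 on the groups compared, 83 with 12 columns, 0 protein-coding and 3 to 13, from 11 higher and 2 lower to 3 and 5, and the cause was not tested. For its 1 lower call (AC073107.2, interaction of SMC5 and doxorubicin) the threshold was not passed with a replicate block (adjusted p = 0.076), with GC-adjusted values (0.0638), at pseudocount 0.1 (1) or at a minimum FPKM of 5 (1), with a range of 5.68e-05 to 1 over its alternatives. NSE4 against SMC5 without doxorubicin (6, all higher) had 7 on the groups compared (1 higher, 6 lower, 1 shared), 21 with no filter, 3 at a minimum FPKM of 5, 3 at pseudocount 0.1, 2 protein-coding, 2 above 0 in every sample and 11 to 16. With doxorubicin (9) it had 575 with no filter, 0 on the groups compared, 139 with 12 columns, 1 protein-coding, 5 GC-adjusted, 4 above 0 in every sample and 5 to 12. Shared loci of the 2 plasmids (0 and 1) were 28 and 14 at an unadjusted p under 0.01.

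Named genes whose sign turned were not called. Leaving out 1 library for SMC5, doxorubicin in GFP cells gave −1.461 to 0.362 and doxorubicin in NSE4 cells −0.642 to 1.237. For SMC5, NSE4 without doxorubicin ran from −1.2 to 0.623, and for SMC5, NSE4 with doxorubicin ran from −0.38 to 1.498. For SMC5, interaction of NSE4 and doxorubicin gave −0.092 to 1.786, and that of SMC5 −0.553 to 1.27. COL1A1 ran from −0.198 to 0.51 in GFP cells and NSMCE4A from −0.194 to 0.199 in SMC5 cells. Quantile normalization gave SMC5 0.14 and NSMCE4A −0.025 for doxorubicin in SMC5 cells. NSMCE4A in SMC5 cells with doxorubicin had an adjusted p of 0.00184 with 12 columns and 0.0276 with no filter.

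Among the 32 gene list calls the median changed sign or reached 0 under a scaling only for mitochondrial mRNAs, under quantile normalization (NSE4 without doxorubicin −0.04, NSE4 against SMC5 0.00). Of these calls an estimated correlation ended all 32, those of the p53 target list among them, and fry kept 12. A call lost with an estimated correlation therefore does not set 1 list apart from another. Fry kept the p53 target, cholesterol synthesis and pro-apoptotic lists for doxorubicin in each background. In GFP cells its adjusted p was 6.33e-05, 2.95e-04 and 0.00467, and in NSE4 cells 6.39e-05, 2.51e-04 and 0.00788. It also kept recombination genes in GFP cells (0.0298) and the SMC5/6 list for NSE4 without (0.00204) and with doxorubicin (0.00451). For doxorubicin fry also called lists that camera did not, in GFP cells those given in the results. In NSE4 cells these were antigen presentation (0.0499) and hepatocyte and neural loci (0.00356), and in SMC5 cells Wnt target (0.0463) and hepatocyte and neural loci (0.00148). The interferon-stimulated calls did not pass it, at 0.544 for NSE4 and 0.273 for SMC5 without doxorubicin. A replicate block kept 29, losing the SMC5/6 list for NSE4 without (0.1) and with doxorubicin (0.0561) and histones for NSE4 against SMC5 (0.0538). Loci of 1 gene kept 31, losing mitochondrial mRNAs for NSE4 (0.161). GC adjustment kept 28, losing the SMC5/6 list for NSE4 (0.0672), mitochondrial mRNAs (0.0644 and 0.0511) and histones (0.0624).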

Other observations

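The tests of carry-over, of a low GFP sample and of the ribosomal protein list and its scalings were chosen after the values were seen, and GC-adjusted values were added after the data were seen but before their own result was. So were the rule that a verdict needs the whole interval on one side of its bound and the rule that replicate differences of 1 direction give no verdict. Messenger RNAs of cytosolic ribosomal proteins fell with doxorubicin in each background. Of 43 such genes 39 fell in GFP cells, 39 in NSE4 cells and 35 in SMC5 cells, and 0 rose, with median log2 changes of −0.79, −0.75 and −0.80. Camera gave p = 6.92e-24, 2.35e-24 and 2.56e-25, and p = 0.0314, 0.0303 and 0.0282 with an estimated correlation, over limma's fit. These p-values and those below are not adjusted over lists, unlike those of the planned lists, and cannot be set beside them. The medians were −0.80, −0.76 and −0.80 under median-of-ratios scaling, and smaller under quantile normalization, at −0.44, −0.37 and −0.40 with 37, 36 and 35 of 43 genes below 0. In the comparisons of plasmids 0 of these genes passed. Camera gave p = 7.61e-07 for NSE4 without and 1.4e-05 with doxorubicin, 0.0189 and 0.208 for SMC5, and 0.00595 and 0.00649 for NSE4 against SMC5, at medians of 0.01 to 0.09, against p = 0.206 to 0.727 with an estimated correlation. The ribosome biogenesis list of the report was not called, and NPM1 and FBL, which are on it, fell.

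Long genes were lower after doxorubicin. Across 9563 protein-coding loci Spearman rho of gene length and log2 fold change was −0.235 in GFP cells, −0.215 in NSE4 cells and −0.217 in SMC5 cells. In GFP cells the median change was 0.13 in the shortest group of 2391 loci (up to 14.2 kb), where 619 rose and 333 fell, and −0.19 in the longest (from 83.6 kb), where 220 rose and 615 fell. Transcript length, which enters FPKM, is argued against, since with it held constant rho was −0.244 in GFP cells (104% kept). With GC content held constant rho was −0.191 in GFP cells, 81.6% kept (interval 77.8 to 84.8 over 1000 resamples, against a bound of 80%). It was −0.164 in NSE4 cells (76.3% kept, 72.4 to 80.1) and −0.165 in SMC5 cells (76.1%, 72.3 to 79.7), less than in GFP cells, for which the bound was set. In GFP cells the share kept met the prediction set beforehand against GC content, and only the later interval rule withheld that verdict. A part played by GC content stays open. No biological explanation of this trend was tested.

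Interferon-stimulated loci lay higher with either plasmid than in GFP cells without doxorubicin. Both comparisons subtract the same 2 GFP libraries, so they are not 2 independent results. A low level in both GFP libraries would raise both medians, which leaving out 1 library cannot show and which was not tested. A single low GFP library is argued against, since the lowest median without a GFP library was 0.17. So is a GC trend as the source of the call, since camera on GC-adjusted values kept an adjusted p of at most 2.04e-10. Camera with an estimated correlation did not call the list, at adjusted p = 0.455 for NSE4 and adjusted p = 0.462 for SMC5. That setting ended all 32 list calls, so the loss here does not speak against this list in particular. Fry did not call the list either (adjusted p = 0.544 and 0.273), and 0 of 25 loci passed in either comparison. Replicate 1 lay below replicate 2 in this list in each of the 5 groups with 2 samples, by a median of 0.227 and 0.159 in doxorubicin-treated GFP and NSE4 cells and of 0.124, 0.086 and 0.038 in untreated GFP, NSE4 and SMC5 cells. The mitochondrial share of FPKM was higher in replicate 1 of each of these groups. A shift shared by replicate 1 cancels between groups with both replicates, so these differences are not the spread to set the medians of 0.20 in NSE4 and 0.27 in SMC5 cells against. By the prediction set beforehand, a difference at least as large as the smaller median would count for genes of the list moving together. The 0.227 met it, and only the later rule on differences of 1 direction withheld that verdict. Whether genes of the list moving together account for those medians stays open. IFNL1 and IFI6 did not pass. An answer of the cells to the plasmid DNA or its product was not tested.

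SMC5 was uneven in cells without its plasmid, with a root mean square log2 difference of 1.517 between the libraries of a group against a median of 0.21. Of 7936 loci of 5 to 50 FPKM 73 (0.92%, exact interval 0.722 to 1.16, with loci taken as independent) were as uneven. The share itself met the prediction set beforehand against ordinary spread, which was a share under 1%. The interval, required by the rule added later, spans that bound, so ordinary spread stays open. Carry-over from SMC5 cells would need at most 2.95% of their level. NSMCE4A, the other plasmid gene, showed no excess of that size. It was even in GFP cells (71.8 ± 4.31 FPKM) and lower in SMC5 cells (37.8 ± 7.43 FPKM), against 4128 FPKM in NSE4 cells. That speaks against carry-over of that size from every plasmid library, but not from SMC5 libraries alone, which stays open. A smaller carry-over of NSMCE4A into GFP cells, which lay above SMC5 cells, is not excluded. With this spread SMC5 missed the threshold in its own cells at log2 differences of 5.66 and 6.02.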
